A study of Oryza sativa with 18 samples.

How the data were processed

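Polyadenylated RNA of rice flag leaves at grain filling was sequenced from 18 strand-specific libraries on a NovaSeq X Plus, per the labels. They form 6 groups of 3 replicates: Hanyou73, Hanhui3 and Huhan7B, each in water and under drought. Groups were read from the sample labels and matched to the file columns by their names. The same field, growth stage and time of day are stated for all groups. Per the submitters' processing notes, reads were processed with fastp, HISAT2, StringTie, RSEM and DESeq2 on the IRGSP-1.0 build, with no versions or settings given.

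The values deposited by the authors are FPKM, a unit that neither the header nor the labels name. It was inferred from the values, which carry 2 decimals, sum to between 958893 and 1140989 per library where TPM would have equal sums, and follow an effective length. The file also holds group means and a gene length, per the file headers. Counts were not used here. The plan made before the data were examined assumed counts, with a written fallback for FPKM, and that fallback was used: limma-trend on log2(FPKM + 1).

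Depth was estimated from the steps between low values of genes of 700 to 2500 bases. With 310 bases taken off the length, 74.8% to 80.0% of low values were whole read numbers within 0.1, which gives 13.1 to 16.5 M fragments per library. The variance between replicates was 1.42 to 2.02 times the Poisson variance for genes of 20 to 100 reads and 2.50 to 17.0 times for the genes with most reads. Structural RNA took 0.43% to 0.992% of FPKM, genes of the organelles 0.065% to 0.151%, and the most abundant gene 2.93% to 7.69%.

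Of 38993 genes listed, 6938 were 0 in all libraries. Genes were tested where FPKM reached 1 in at least 3 libraries, and 1017 structural RNA genes were left out, which kept 22590 genes. The filter and the exclusion were chosen after the values were seen. Symbols (11321 genes) and products (27431 genes) came from the gene names and descriptions in the deposited file. A RefSeq gene table, matched for 12188 genes, gave further symbols and synonyms. Its assembly differs from the authors' build, so no coordinates are given.

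limma 3.58.1 in R 4.3.3 fitted 6 group means with an intensity trend, and two-sided moderated t-tests of contrasts were adjusted by Benjamini-Hochberg with a threshold of 0.05. The contrasts were the drought response of each genotype, the hybrid's response minus the parental mean, the parents' difference in response, the hybrid against the mean of the parents in log2, and the parents against each other. A gene lay outside both parents where it was called against each in the same direction, and its log2 value is the difference from the nearer parent, with no SE. Errors of log2 changes are the moderated SE of the fit, and those of levels are SD over 3 libraries. A log2 change from a group near zero depends on the pseudocount of 1 and is no bound. RAB16A was listed at 0 in both parents' watered libraries and SWEET15 in all watered libraries, so log2 values against these groups depend on the pseudocount and no fold is given. LEA3 was listed at 0.12 FPKM or less in watered Hanhui3 and 0.18 or less in watered Huhan7B. Its log2 values against these groups depend on the pseudocount too. Genes expressed in a single parent were on at an FPKM of 1 or more and off under 0.1 in all 3 libraries.

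Gene lists were fixed before the data were examined. From 33 lists, 208 genes whose product name showed another function under a like symbol were dropped before any test and 1998 were kept. A list was tested where at least 3 members passed the filter, which left 32 lists. camera, which tests a list against the other genes, used a preset correlation of 0.01 and was repeated with an estimated correlation per list. fry, which tests a list against no change, asks another question and was run beside it. All lists of a comparison were adjusted together. The calls that hold with an estimated correlation number 3 in Hanyou73, 12 in Huhan7B, 5 for the hybrid's response minus the parental mean, and 4 and 6 for the hybrid against mid-parent in water and drought. In Hanhui3 camera left 0, with 7 at an unadjusted p under 0.05 and 30 by fry. The 4 lists called in no comparison had these results in Hanyou73's response: C4-type enzymes, 8 of 19 up and 9 down (adjusted p = 0.281); sucrose cleavage, 12 of 31 up and 8 down (0.469). Proline genes had 3 of 4 up and 1 down (0.469), and pollen and flower markers 2 of 6 up (0.763).

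Marker lists of other tissues named 114 genes of dividing cells, 57 of grain, 40 of pollen and flower and 48 of stem and vascular tissue. The leaves expressed 64, 2, 6 and 27 of them, and the grain list was too small to test. KEGG pathways of 10 to 500 members, as annotated in the deposited file, were tested by one-sided Fisher's exact tests over 126 pathways and 5018 annotated genes. GO terms were not tested. Named genes were up to 8 called genes per direction and comparison with the largest log2 change, with a mean of at least 5 FPKM, values that do not overlap between groups and a named product. For differences of responses, values were allowed to overlap. Up to 4 members of each list by smallest p and fixed drought markers were added, and OsRcaII stands for Rubisco activase.

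The method was tested on simulated data with 200 changed genes in Hanyou73's response. At a log2 change of 0.5, 34 of 42 well-expressed genes were recovered (81%), at 1, 41 of 44 (93.2%) and at 2, 46 of 46 (100%), with 14 false calls. In a contrast with no change limma called 0 genes, with 1164 at an unadjusted p under 0.05. For lists, camera called 0 in an unchanged comparison, with 3 at an unadjusted p under 0.05, and 1 where 1 list was raised. Genes vary independently in these simulations, so the 0 does not cover lists whose genes vary together.

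Alternatives planned before the data were examined were no filter, a replicate block, only the groups compared, a 2-fold threshold, single libraries left out, an arithmetic mid-parent and other on and off levels. Median-ratio scaling of FPKM, a pseudocount of 0.1, an FPKM of at least 5 and equal sums were added after the values were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the values and drew the figures.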

Results

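The transcriptome of rice flag leaves was measured at grain filling in Hanyou73, a hybrid bred for drought tolerance, and in its parental lines Hanhui3 and Huhan7B. Each genotype was sampled in watered plots and after irrigation was withheld, which gave 6 groups of 3 libraries and 18 libraries in all. Each library came from a pool of leaves of plants that shared a plot, so errors and p-values describe the spread between pools and not between plots. The deposited values are FPKM for 38993 genes, and they summed to between 958893 and 1140989 per library. Between 19088 and 21021 genes reached an FPKM of 1. The steps between the lowest values correspond to a depth of 13.1 to 16.5 M fragments per library. Libraries of the same group correlated with Pearson's r of 0.982 to 0.989 across genes, against 0.837 to 0.958 between groups. These values are across genes, which are not independent replicates. The first 3 principal components held 34.8%, 29.0% and 17.1% of the variance.

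**Figure D1:**
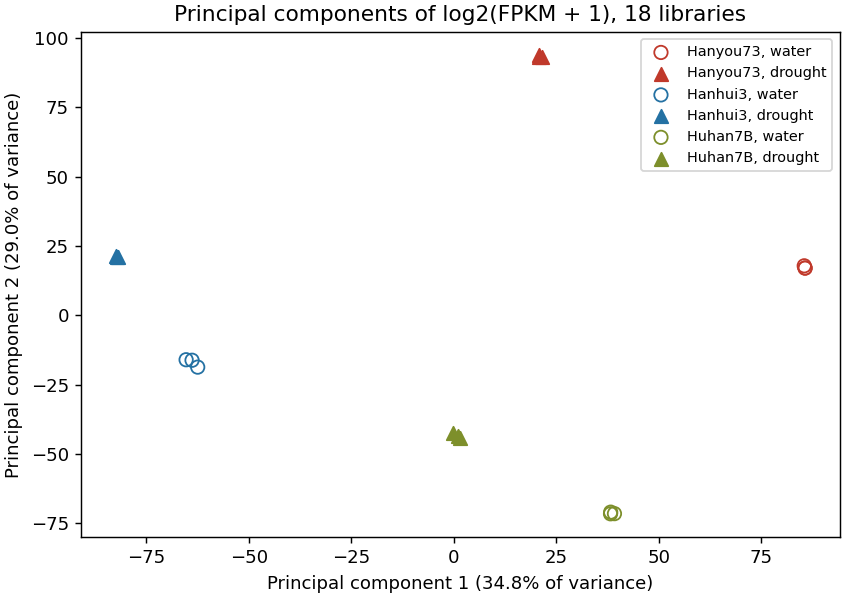
Scores of the 18 libraries on the first and the second principal component of log2(FPKM + 1), with the percent of variance on each axis, coloured by genotype and with open symbols for water and filled symbols for drought. The 3 libraries of each group lie together, and the components hold 34.8% and 29.0% of the variance.

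The first comparison asked how the hybrid leaf responded to drought. LEA3 (Os05g0542500), a group 3 late embryogenesis abundant protein, went from 1.11 ± 0.209 FPKM in water to 146.0 ± 6.59 under drought (SD, n = 3), a log2 change of 6.13 ± 0.12 (SE). The dehydrin RAB16B (Os11g0454200) went from 0.60 ± 0.209 to 242.9 ± 8.33 FPKM (SD, n = 3). The regulators OsDREB1B (Os09g0522000), a factor that binds drought-responsive promoter elements, and ERF102 (Os09g0457900), of the ethylene response family, rose by 5.81 ± 0.10 and 6.48 ± 0.14 in log2 (SE, n = 3). Fixed drought markers also rose, among them NCED3 (Os03g0645900), whose enzyme makes the precursor of abscisic acid, by 1.63 ± 0.12, and P5CS1 (Os05g0455500), which makes proline, by 1.53 ± 0.06. SNAC1 (Os03g0815100), a stress NAC factor, rose by 1.36 ± 0.07, and bZIP23 (Os02g0766700), a factor of abscisic acid signalling, by 1.92 ± 0.07 (SE, n = 3). RAB16A (Os11g0454300), another dehydrin, stood at 0.0567 ± 0.0982 FPKM in water (SD, n = 3), near zero, and its fitted log2 change was 7.16 ± 0.14 (SE). These single genes do not stand for their classes. The fixed list of drought transcription factors, with 17 of 39 up and 17 down, was not called (camera adjusted p = 0.435). Nor was abscisic acid metabolism, with 8 of 15 up and 6 down (camera adjusted p = 0.936).

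Other genes fell in the hybrid under drought. OsCML21 (Os05g0312600), a probable calcium-binding protein, dropped from 196.5 ± 10.8 to 1.85 ± 0.202 FPKM, and the ammonium transporter AMT3 (Os03g0838400) from 324.3 ± 6.52 to 8.42 ± 0.365 (SD, n = 3). The boron transporter BOR2 (Os01g0175700) dropped from 75.4 ± 0.738 to 0.407 ± 0.240 FPKM (SD, n = 3). SGR (Os09g0532000), which starts chlorophyll breakdown, dropped from 544.7 ± 11.3 to 73.5 ± 2.77 FPKM (SD, n = 3).

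Of 32 gene lists fixed beforehand, 9 stood apart from the other genes in the hybrid's response, 7 of them upwards. Of the 24 LEA and dehydrin genes tested, 22 rose (23 rose and 1 fell adjusted over the list alone), with a median log2 change of 2.22 (camera adjusted p = 5.7e-08; adjusted p = 0.00256 with an estimated correlation). Of the 32 Calvin cycle genes, 25 rose (25 adjusted over the list alone), with a median of 0.81 (adjusted p = 8.9e-07; adjusted p = 0.0167 with an estimated correlation). Within that list RbcS3 (Os12g0291100), a small subunit of Rubisco, went from 1989 ± 58.6 to 9193 ± 40.3 FPKM (SD, n = 3). Of the 74 defence genes, 52 rose and 9 fell, as many adjusted over the list alone, with a median of 0.98 (adjusted p = 0.000877; adjusted p = 0.00429 with an estimated correlation). JIOsPR10 (Os03g0300400), a pathogenesis-related protein, rose by 5.21 ± 0.13, and RBBI2-2 (Os01g0123900), a trypsin inhibitor, by 4.24 ± 0.07 (SE, n = 3).

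Among the 228 cytosolic ribosomal protein genes, 178 rose and 4 fell (180 and 4 adjusted over the list alone), with a median of 0.49, or 0.32 with median-ratio scaling (adjusted p = 1.62e-08; adjusted p = 0.198 with an estimated correlation). Of the 33 abscisic acid signalling genes, 22 rose and 6 fell, as many adjusted over the list alone (adjusted p = 0.00619; adjusted p = 0.0669 with an estimated correlation). They included BZIP12 (Os01g0867300), up by 2.94 ± 0.07, and the phosphatase OsPP2C49 (Os05g0457200), up by 3.72 ± 0.11 (SE, n = 3). Starch synthesis genes rose in 18 of 22 cases and fell in 2, as many adjusted over the list alone (adjusted p = 0.00256; adjusted p = 0.0904 with an estimated correlation), with SSI (Os06g0160700), a soluble starch synthase, up by 1.47 ± 0.05 (SE, n = 3). Lignin and phenylpropanoid genes fell in 25 of 53 cases and rose in 16 (27 and 17 adjusted over the list alone; adjusted p = 0.00619; adjusted p = 0.21 with an estimated correlation). The cinnamyl alcohol dehydrogenase gene GH2 (Os02g0187800) fell by 4.19 ± 0.11 in log2 (SE, n = 3). Of 10 clock genes, 8 fell and 2 rose, as many adjusted over the list alone (adjusted p = 0.0374; adjusted p = 0.21 with an estimated correlation; 0.0598 with an FPKM of at least 5). OsPRR95 (Os09g0532400), a pseudo-response regulator, fell by 1.23 ± 0.03 and LHY (Os04g0583900), whose product is named REVEILLE 2, rose by 2.52 ± 0.09 (SE, n = 3).

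Markers of stem and vascular tissue moved with the hybrid's drought response, with 18 of 27 up and 5 down (19 and 5 adjusted over the list alone; adjusted p = 0.0193; adjusted p = 0.0669 with an estimated correlation). CESA7 (Os10g0467800), a cellulose synthase of secondary walls, went from 0.02 ± 0.0346 to 12.6 ± 0.223 FPKM, while the laccase gene OsLAC7 (Os01g0850550) went from 47.4 ± 2.21 to 0.597 ± 0.161 (SD, n = 3). The list no longer passed with an FPKM of at least 5 required (adjusted p = 0.138) or with a pseudocount of 0.1 (adjusted p = 0.0589). In KEGG pathways, genes that fell at least 2-fold were concentrated in glutathione metabolism, with 36 of 111 members against 8.8 expected (Fisher's exact test, adjusted p = 5.05e-12). Phenylpropanoid biosynthesis followed with 26 of 106 against 8.4 (adjusted p = 7.13e-06). Genes that rose at least 2-fold were concentrated in photosynthesis, with 21 of 68 against 7.7 (adjusted p = 0.00137), while antenna proteins had 7 of 16 down against 1.3 (adjusted p = 0.00288) and porphyrin metabolism 11 of 53 down against 4.2 (adjusted p = 0.0421). The fixed list of photosystem and light-harvesting genes, with 37 of 64 up and 16 down (38 and 16 adjusted over the list alone), was not called (adjusted p = 0.116). In total 15977 of 22590 genes tested changed, 10161 up and 5816 down, and 4594 of them by at least 2-fold. The median tested gene rose by 0.18 in log2, and with median-ratio scaling, which puts that median at 0.022, the split became 7891 up and 7460 down.

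**Figure D2:**
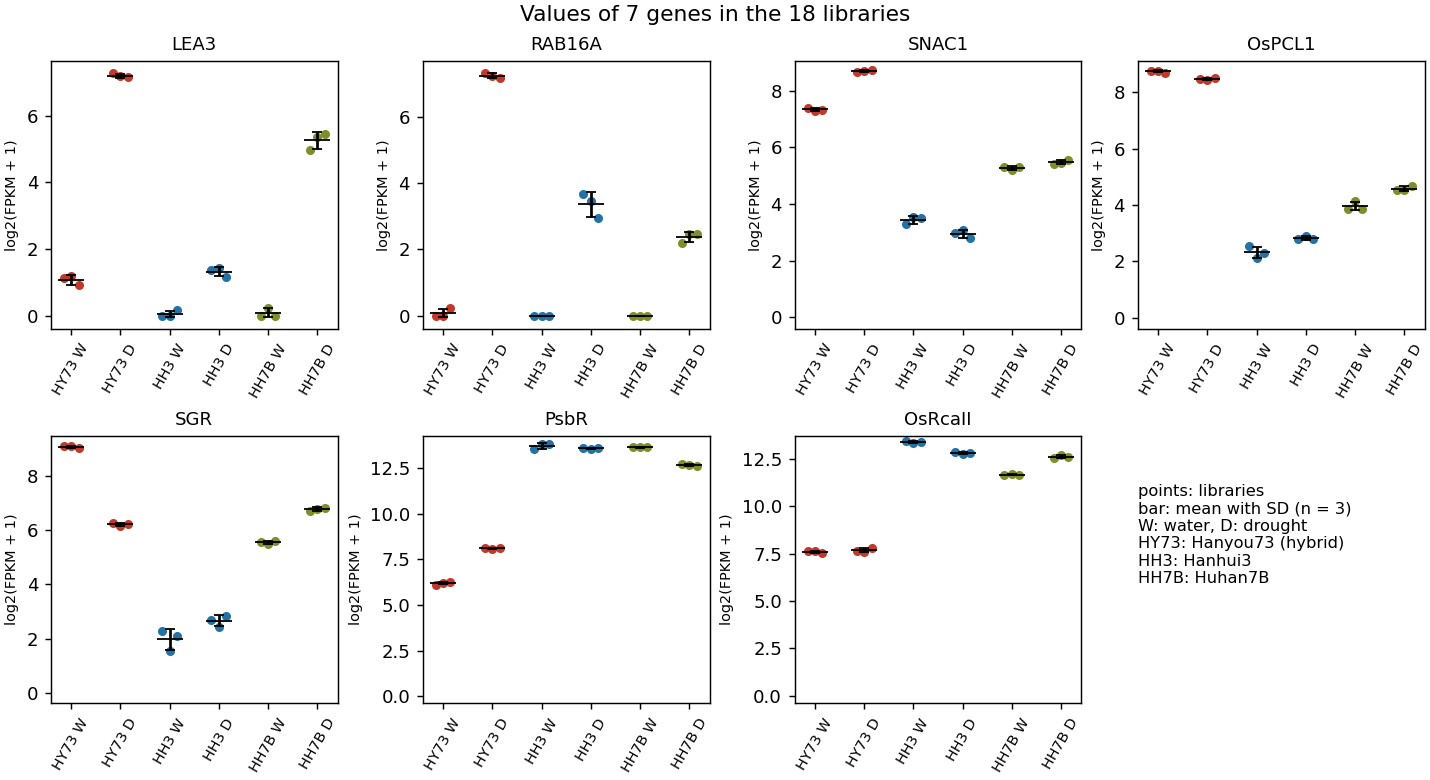
Values of LEA3, RAB16A, SNAC1, OsPCL1, SGR, PsbR and OsRcaII in log2(FPKM + 1) for the 18 libraries, with the group mean and its SD (n = 3). The photosystem gene PsbR sits at 72.7 and 276.4 FPKM in the hybrid in water and drought and at 6612 FPKM or more in the parents.

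The same question was asked of Hanhui3, a parent of the hybrid. The lipid-transfer gene LTP2-A (Os11g0115350) went from 1.00 ± 0.641 to 234.9 ± 2.41 FPKM, and the raffinose synthase gene Os07g0209100 from 7.45 ± 1.46 to 333.9 ± 8.09 (SD, n = 3). OsLOX11 (Os12g0559200), a lipoxygenase, rose from 0.21 ± 0.106 to 26.4 ± 0.692 FPKM (SD, n = 3). SUT1 (Os03g0170900), which loads sucrose into the phloem, rose by 1.42 ± 0.04 in log2, and AGPL3 (Os05g0580000), of starch synthesis, by 2.42 ± 0.11 (SE, n = 3). NCED3 (Os03g0645900) and SNAC1 (Os03g0815100) fell, by 1.30 ± 0.12 and 0.49 ± 0.07 in log2 (SE, n = 3). LEA3 (Os05g0542500) reached 1.503 ± 0.235 FPKM under drought from 0.04 ± 0.0693 in water (SD, n = 3).

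In Hanhui3, 7 of the 32 lists were called. With an estimated correlation camera called 0, against 7 at an unadjusted p under 0.05. fry, which tests a list against no change and not against the other genes, called 30. Of 228 cytosolic ribosomal protein genes, 44 were not called, 2 fell and the others rose (186 up and 2 down adjusted over the list alone), with a median of 0.41 (adjusted p = 8.57e-14; adjusted p = 0.119 with an estimated correlation). Abscisic acid signalling genes rose in 22 of 33 cases and fell in 3 (23 and 3 adjusted over the list alone; adjusted p = 0.00158; adjusted p = 0.081 with an estimated correlation). LEA and dehydrin genes rose in 14 of 24 cases and fell in 1, as many adjusted over the list alone (adjusted p = 0.00572; adjusted p = 0.081 with an estimated correlation). Antioxidant enzyme genes rose in 26 of 37 cases and fell in 6, as many adjusted over the list alone (adjusted p = 0.00906; adjusted p = 0.252 with an estimated correlation). Among them Cu-Zn-SOD (Os07g0665200), a superoxide dismutase, rose by 2.27 ± 0.06 in log2 (SE, n = 3). Drought transcription factors fell in 13 of 39 cases and rose in 7, as many adjusted over the list alone (adjusted p = 0.016; adjusted p = 0.0916 with an estimated correlation). OsDREB1B (Os09g0522000) fell by 1.72 ± 0.10 and OsDREB1A (Os09g0522200) by 1.56 ± 0.15 in log2 (SE, n = 3).

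Markers of dividing cells, such as the histone gene H1 (Os04g0253000, up by 1.19 ± 0.04 in log2; SE, n = 3), moved with drought in Hanhui3. They rose in 34 of 64 cases and fell in 3, as many adjusted over the list alone (adjusted p = 0.0207; adjusted p = 0.0916 with an estimated correlation; 0.105 without a filter on low values). Trehalose genes fell in 7 of 15 cases and rose in 3, as many adjusted over the list alone (adjusted p = 0.0254; adjusted p = 0.0916 with an estimated correlation). That call was lost without Hanhui3 water replicate 1 (adjusted p = 0.0547) and without the filter (adjusted p = 0.0591). Among KEGG pathways, plant hormone signal transduction held 26 of 301 members up at least 2-fold against 11.7 expected (Fisher's exact test, adjusted p = 0.00523). In total 12098 genes changed, 7934 up and 4164 down, with 1611 changed at least 2-fold. The median gene rose by 0.10 in log2, and median-ratio scaling gave 5784 up and 5756 down.

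The question was also asked of Huhan7B, the other parent. OsEnS-107 (Os07g0529000), an isocitrate lyase of the glyoxylate cycle, went from 3.83 ± 0.206 to 130.7 ± 10.8 FPKM, and MS (Os04g0486950), a malate synthase of the same cycle, from 1.75 ± 0.345 to 57.9 ± 3.69 (SD, n = 3). CP (Os08g0556900), a cysteine endopeptidase, rose by 3.96 ± 0.08 in log2 (SE, n = 3). LEA3 (Os05g0542500) rose from 0.06 ± 0.104 to 37.8 ± 6.59 FPKM (SD, n = 3), and NCED3 (Os03g0645900) by 1.28 ± 0.12 in log2 (SE, n = 3). OsBDG1 (Os11g0514400), a leucine-rich repeat protein, dropped from 442.7 ± 5.99 to 9.72 ± 0.156 FPKM, and the chitinase gene Cht11 (Os03g0132900) from 117.0 ± 8.36 to 5.30 ± 0.667 (SD, n = 3). SNAC1 (Os03g0815100) rose by 0.22 ± 0.07 in log2 (SE, n = 3), and that call was lost without Huhan7B drought replicate 3 (adjusted p = 0.0831) and without Huhan7B water replicate 2 (adjusted p = 0.0772).

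Huhan7B had 17 called lists, of which 12 held with an estimated correlation. Calvin cycle genes rose in 23 of 32 cases and fell in 1, as many adjusted over the list alone, with a median of 0.62 (adjusted p = 5.38e-12). Photosystem and light-harvesting genes rose in 44 of 64 cases and fell in 7 (47 and 7 adjusted over the list alone; adjusted p = 3.2e-11), with PSBS2 (Os04g0690800), of heat dissipation in photosystem II, up by 2.55 ± 0.06 in log2 (SE, n = 3). Genes of chlorophyll synthesis rose in 19 of 29 cases and fell in 4 (adjusted p = 6.93e-06), as many adjusted over the list alone. Genes of chlorophyll breakdown rose in 17 of 23 and fell in 2 (17 and 3 adjusted over the list alone; adjusted p = 1.26e-05). Photorespiration genes rose in 18 of 32 cases and fell in 5, as many adjusted over the list alone (adjusted p = 2.45e-05), with OsGDCH (Os10g0516100), of the glycine cleavage system, up by 1.501 ± 0.05 in log2 (SE, n = 3).

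In Huhan7B starch synthesis genes rose in 16 of 22 cases and fell in 2 (adjusted p = 3.59e-05), and starch degradation genes in 15 of 29 and 4 (adjusted p = 0.00319), both as many adjusted over the list alone. Sucrose synthesis and transport genes rose in 13 of 30 cases and fell in 4, as many adjusted over the list alone (adjusted p = 0.00275). Raffinose and galactinol genes rose in 7 of 11 cases and fell in 2 (8 and 2 adjusted over the list alone; adjusted p = 0.00567; adjusted p = 0.105 with an estimated correlation), with OsGolS1 (Os03g0316200), a galactinol synthase, up by 2.02 ± 0.12 in log2 (SE, n = 3). Genes of abscisic acid signalling rose in 22 of 33 cases and fell in 3 (22 and 4 adjusted over the list alone; adjusted p = 5.98e-07). Abscisic acid metabolism genes rose in 8 of 15 and fell in 3 (9 and 3 adjusted over the list alone; adjusted p = 0.0118; adjusted p = 0.195 with an estimated correlation). LEA and dehydrin genes rose in 17 of 24 cases and fell in 4, as many adjusted over the list alone (adjusted p = 8.88e-06). Cuticle and wax genes rose in 13 of 29 cases and fell in 4, as many adjusted over the list alone (adjusted p = 0.0129; adjusted p = 0.0873 with an estimated correlation; 0.0808 with an FPKM of at least 5).

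Further lists fell in Huhan7B. Cytosolic ribosomal protein genes fell in 164 of 228 cases and rose in 5, as many adjusted over the list alone, with a median of -0.35 (adjusted p = 5.09e-11; adjusted p = 0.0873 with an estimated correlation). Markers of dividing cells fell in 35 of 64 cases and rose in 3 (36 and 3 adjusted over the list alone; adjusted p = 9.32e-05). Genes of the TCA cycle fell in 25 of 34 cases and rose in 1, as many adjusted over the list alone (adjusted p = 3.63e-05). Glycolysis genes fell in 24 of 47 cases and rose in 7 (25 and 8 adjusted over the list alone; adjusted p = 0.0259; adjusted p = 0.105 with an estimated correlation), with OsPGK2 (Os02g0169300), a cytosolic phosphoglycerate kinase, down to 45.2 ± 0.683 from 121.7 ± 3.77 FPKM (SD, n = 3). Diterpenoid biosynthesis held 11 of 38 members down at least 2-fold against 1.5 expected (Fisher's exact test, adjusted p = 1.47e-05), while the KEGG ribosome pathway held 27 of 354 up at least 2-fold against 11.9 (adjusted p = 0.00231) but, with no threshold of fold, 197 of 354 down against 141.8 (adjusted p = 3.68e-08). In total 12037 genes changed, 4781 up and 7256 down, with 1681 changed at least 2-fold. The median gene moved by -0.065 in log2, and median-ratio scaling turned the balance to 6033 up and 5555 down.

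A further comparison asked which responses the 3 genotypes had in common. In all 3, 2042 genes rose and 1400 fell, 3442 in total, against 755 and 344 for independent lists of the same sizes. At least 2-fold, 162 genes rose in all 3 against 4 for independent lists, and 87 fell against 2. RAB16B (Os11g0454200) was among the shared risers, at 19.2 ± 1.64 FPKM under drought in Hanhui3 and 16.7 ± 1.22 in Huhan7B (SD, n = 3). The raffinose synthase gene Os07g0209100 rose by 5.00 ± 0.10, 5.32 ± 0.10 and 2.99 ± 0.10 in log2 in Hanyou73, Hanhui3 and Huhan7B (SE, n = 3). Of genes called in both genotypes of a pair, 84.1% had the same direction in Hanyou73 and Hanhui3, 68.6% in Hanyou73 and Huhan7B, and 59.4% in the parents. Among genes changed at least 2-fold in both, the shares were 93.5%, 91.1% and 87.7%. These responses share no libraries.

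The next comparison tested whether the hybrid's drought response differed from the mean response of its parents. OsDREB1B (Os09g0522000) differed by 6.41 ± 0.12 in log2 (SE, n = 3): it stood at 203.0 ± 5.31 FPKM in the droughted hybrid, 5.41 ± 0.402 in Hanhui3 and 33.0 ± 1.76 in Huhan7B (SD, n = 3). ERF102 (Os09g0457900) differed by 6.28 ± 0.18 and JIOsPR10 (Os03g0300400) by 5.14 ± 0.16 (SE, n = 3). LEA3 (Os05g0542500) differed by 2.90 ± 0.15, SNAC1 (Os03g0815100) by 1.49 ± 0.09 and RbcS3 (Os12g0291100) by 1.35 ± 0.04 (SE, n = 3). LEA3 was near zero in both watered parents, so the size of its difference depends on the pseudocount. The sugar transporter genes SUT1 (Os03g0170900) and SWEET14 (Os11g0508600) differed by -0.72 ± 0.05 and -1.68 ± 0.15 (SE, n = 3), while the list of sucrose synthesis and transport, with 14 of 30 members higher and 6 lower (15 and 6 adjusted over the list alone), was not called (adjusted p = 0.677). OsCML21 (Os05g0312600) differed by -5.25 ± 0.20 and SGR (Os09g0532000) by -3.82 ± 0.17 (SE, n = 3). In water, SGR ran from 531.67 to 552.22 FPKM in the hybrid libraries, 1.9 to 3.88 in Hanhui3 and 44.52 to 47.99 in Huhan7B. Under drought it ran from 70.8 to 76.33, 4.4 to 6.21 and 103.14 to 113.65. The droughted hybrid thus lay between its parents, and its larger fall began from a higher watered level.

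In this comparison 13 of 32 lists were called, and 5 of them held with an estimated correlation. LEA and dehydrin genes had a higher log2 response in the hybrid in 20 of 24 cases (21 higher and 1 lower adjusted over the list alone), with a median of 1.47 (adjusted p = 1.36e-07). The difference was positive for 51 of 74 defence genes and negative for 7 (51 and 8 adjusted over the list alone; adjusted p = 1.97e-05). Stem and vascular markers had a positive difference in 19 of 27 cases and a negative one in 3, as many adjusted over the list alone (adjusted p = 0.000347). Chlorophyll breakdown genes had a negative difference in 13 of 23 cases and a positive one in 5 (13 and 6 adjusted over the list alone; adjusted p = 0.000715), with OsPAO (Os03g0146400), which opens the chlorophyll ring, at -1.88 ± 0.04 (SE, n = 3). Heat shock genes had 23 of 68 lower and 16 higher, as many adjusted over the list alone (adjusted p = 0.00888), with OsHsp71.1 (Os03g0276500), a chaperone of the 70 kDa class, at -3.47 ± 0.11 (SE, n = 3).

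The other 8 calls of this comparison were lost with an estimated correlation. Cytosolic ribosomal protein genes were higher in 167 of 228 cases and lower in 4 (169 and 4 adjusted over the list alone; adjusted p = 2.13e-09; adjusted p = 0.137 with an estimated correlation). Calvin cycle genes were higher in 22 of 32 cases and lower in 3 (adjusted p = 0.000413; adjusted p = 0.0558 with an estimated correlation), and dividing-cell markers in 37 of 64 and 3 (adjusted p = 0.0155; adjusted p = 0.0723 with an estimated correlation), both as many adjusted over the list alone. Starch synthesis genes were higher in 17 of 22 cases and lower in 2 (18 and 2 adjusted over the list alone; adjusted p = 0.00888; adjusted p = 0.137 with an estimated correlation). Lignin genes were lower in 25 of 53 cases and higher in 13 (adjusted p = 0.00104; adjusted p = 0.137 with an estimated correlation), and jasmonate genes lower in 20 of 43 and higher in 11 (adjusted p = 0.0073; adjusted p = 0.127 with an estimated correlation), both as many adjusted over the list alone. Clock genes were lower in 6 of 10 cases and higher in 1 (adjusted p = 0.00984; adjusted p = 0.137 with an estimated correlation), and antioxidant genes lower in 17 of 37 and higher in 13 (adjusted p = 0.034; adjusted p = 0.367 with an estimated correlation), both as many adjusted over the list alone. Glutathione metabolism held 27 of 111 members at least 2-fold lower against 6.1 expected (Fisher's exact test, adjusted p = 2.48e-09), and diterpenoid biosynthesis 12 of 38 at least 2-fold higher against 2.7 (adjusted p = 0.000493). In total 13168 genes differed, 8757 higher and 4411 lower in the hybrid, 2996 of them by at least 2-fold. The median gene stood at 0.17 in log2, and median-ratio scaling gave 5890 higher and 5938 lower.

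**Figure D3:**
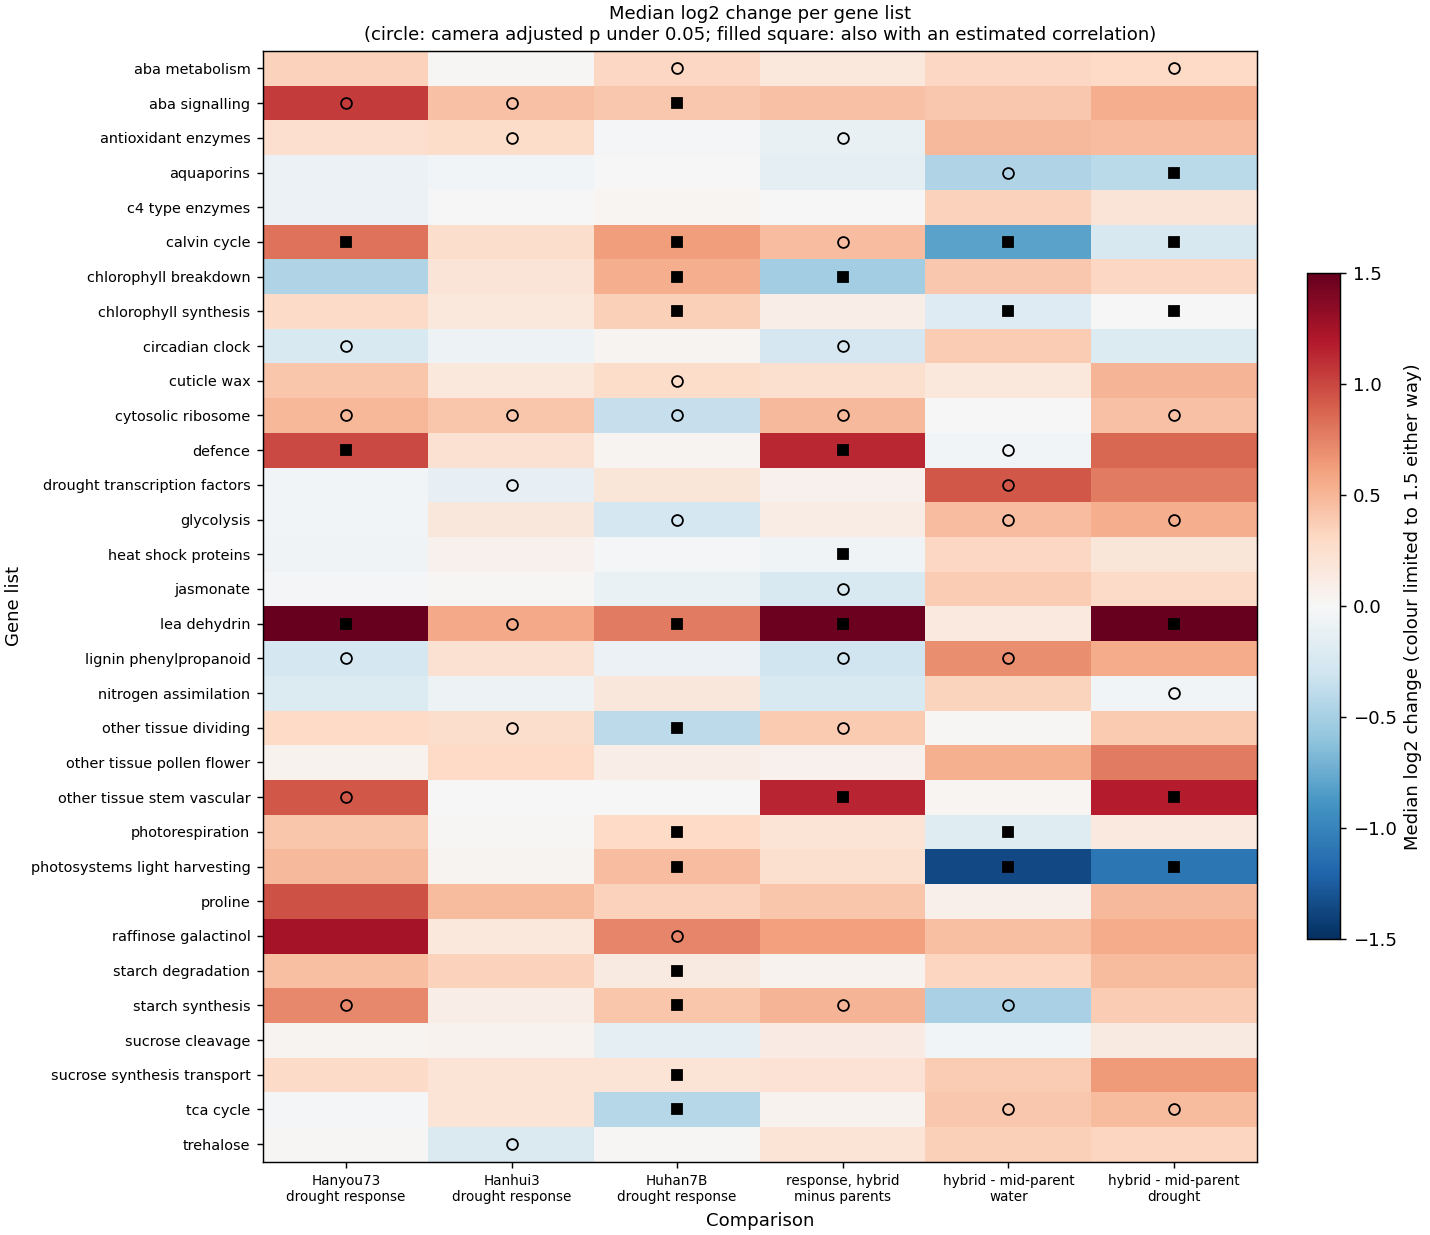
Median log2 change of the members of each of 32 gene lists (colour, limited to 1.5 either way) in 6 comparisons, with circles for a camera adjusted p under 0.05 and filled squares where the call also held with an estimated correlation. LEA and dehydrin genes have a median of 2.22 in the hybrid's drought response, and photosystem genes one of -1.35 for the hybrid against mid-parent in water.

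Whether the parents' responses differed from each other was tested in the same way. CP (Os08g0556900) fell from 10.9 ± 0.764 to 1.42 ± 0.0815 FPKM in Hanhui3 and rose from 2.33 ± 0.313 to 50.7 ± 3.46 in Huhan7B (SD, n = 3), a difference of -6.26 ± 0.12 in log2 (SE, n = 3). OsLOX11 (Os12g0559200) differed by 4.47 ± 0.10 and OsPR1b (Os01g0382000), a pathogenesis-related protein, by 4.44 ± 0.21 (SE, n = 3). LEA3 (Os05g0542500) differed by -3.92 ± 0.17, NCED3 (Os03g0645900) by -2.58 ± 0.18 and SUT1 (Os03g0170900) by 1.48 ± 0.06 (SE, n = 3). The value of LEA3 depends on the pseudocount, as both watered parents were near zero. Protein processing in the endoplasmic reticulum held 46 of 215 members at least 2-fold higher in Hanhui3's response against 18.0 expected (Fisher's exact test, adjusted p = 1.35e-07). In total 12035 genes differed, 8169 higher and 3866 lower in Hanhui3, 2493 of them by at least 2-fold, and median-ratio scaling turned the split to 5147 higher and 5791 lower around a median of 0.18 before scaling.

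The parents were also compared directly in each condition. In water, OsRcaII (Os11g0707000), Rubisco activase, stood at 10790 ± 287 FPKM in Hanhui3 and 3278 ± 99.3 in Huhan7B, while AMT3 (Os03g0838400) stood at 2.70 ± 0.441 and 108.8 ± 6.67 (SD, n = 3). Genes at least 2-fold higher in Hanhui3 were concentrated in carbon fixation, with 21 of 89 members against 6.2 expected (Fisher's exact test, adjusted p = 5.26e-05), and those lower in glutathione metabolism, with 30 of 111 against 10.3 (adjusted p = 5.01e-06). In water 15009 genes differed, 5704 higher and 9305 lower in Hanhui3, and 3822 by at least 2-fold. With a median of -0.12 in log2 before scaling, median-ratio scaling turned this to 7449 higher and 7026 lower. Under drought SUT1 (Os03g0170900) stood at 101.2 ± 1.08 FPKM in Hanhui3 and 23.4 ± 1.23 in Huhan7B (SD, n = 3). Plant hormone signal transduction then held 39 of 301 members at least 2-fold higher in Hanhui3 against 17.9 expected (Fisher's exact test, adjusted p = 0.000251) but, with no threshold of fold, 96 lower against 75.9 (adjusted p = 0.0382). Glutathione metabolism held 18 of 111 at least 2-fold lower against 5.8 (adjusted p = 0.00172). Under drought 13313 genes differed, 7234 higher and 6079 lower in Hanhui3, and 3188 by at least 2-fold, with a median of 0.035 in log2. The balance turned to 6620 higher and 6781 lower with median-ratio scaling and to 6082 and 7177 with equal sums.

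To ask about non-additive expression, the hybrid was compared with the mean of its parents in log2. In water the hybrid had far less transcript of many photosynthesis genes. PsbR (Os07g0147500), of the oxygen-evolving side of photosystem II, stood at 72.7 ± 3.43 FPKM against 13700 ± 1578 in Hanhui3 and 12870 ± 53.5 in Huhan7B (SD, n = 3), a log2 difference of -7.49 ± 0.05 (SE, n = 3). OsRcaII (Os11g0707000) stood at 195.0 ± 7.27 FPKM against 10790 ± 287 and 3278 ± 99.3, and OsPorA (Os04g0678700), a protochlorophyllide reductase, at 13.4 ± 0.710 against 791.7 ± 66.97 and 328.7 ± 7.54 (SD, n = 3). SNAC1 (Os03g0815100) was higher by 2.99 ± 0.06 and the clock gene OsPCL1 (Os01g0971800) by 5.61 ± 0.07 in log2 (SE, n = 3).

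In water 11 lists were called, 4 of them also with an estimated correlation. Photosystem and light-harvesting genes were lower in 39 of 64 cases and higher in 11, as many adjusted over the list alone, with a median of -1.35 (adjusted p = 2e-13; adjusted p = 0.0118 with an estimated correlation). Calvin cycle genes were lower in 23 of 32 and higher in 4 (adjusted p = 6.28e-11), and chlorophyll synthesis genes lower in 15 of 29 and higher in 7 (adjusted p = 0.00064), both as many adjusted over the list alone. Photorespiration genes were lower in 16 of 32 cases and higher in 8 (16 and 9 adjusted over the list alone; adjusted p = 0.00846), with OsSHM1 (Os03g0738400), a serine hydroxymethyltransferase, at -2.77 ± 0.03 in log2 (SE, n = 3). The remaining 7 were lost with an estimated correlation. TCA cycle genes were higher in 28 of 34 cases and lower in 1, as many adjusted over the list alone (adjusted p = 0.0016; adjusted p = 0.0669 with an estimated correlation). Glycolysis genes were higher in 28 of 47 and lower in 5, as many adjusted over the list alone (adjusted p = 0.0223; adjusted p = 0.137 with an estimated correlation). Drought transcription factors were higher in 26 of 39 cases and lower in 3, as many adjusted over the list alone (adjusted p = 0.00846; adjusted p = 0.0667 with an estimated correlation).

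Aquaporin genes were lower in water in 15 of 28 cases and higher in 5 (15 and 6 adjusted over the list alone; adjusted p = 0.00313; adjusted p = 0.208 with an estimated correlation). Starch synthesis genes were lower in 13 of 22 cases and higher in 6, as many adjusted over the list alone (adjusted p = 0.00846; adjusted p = 0.137 with an estimated correlation). Lignin genes were higher in 35 of 53 and lower in 10, as many adjusted over the list alone (adjusted p = 0.0223; adjusted p = 0.337 with an estimated correlation; 0.115 with an FPKM of at least 5 and 0.0718 with equal sums). Defence genes were lower in 32 of 74 and higher in 24, as many adjusted over the list alone (adjusted p = 0.0492; adjusted p = 0.0547 with an estimated correlation; 0.254 with median-ratio scaling, 0.0707 without a filter and 0.0585 with a pseudocount of 0.1). That call was also lost without Hanhui3 water replicate 1 (0.0586), Huhan7B water replicate 3 (0.0572) or Hanyou73 water replicate 3 (0.065). Cytosolic ribosomal protein genes were not called (adjusted p = 0.086) but were called lower with median-ratio scaling (adjusted p = 0.00297). Among KEGG pathways, antenna proteins had 13 of 16 members at least 2-fold lower against 0.8 expected (Fisher's exact test, adjusted p = 8.9e-13), and glutathione metabolism 46 of 111 at least 2-fold higher against 13.0 (adjusted p = 8.01e-14). In total 15190 genes differed, 9876 higher and 5314 lower in the hybrid, with a median of 0.14 and a scaled split of 8003 and 7191, and 3829 differed by at least 2-fold.

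Under drought the hybrid again lay below mid-parent for light-harvesting genes. CP24 (Os04g0457000), an antenna protein of photosystem II, stood at 96.8 ± 3.74 FPKM against 1937 ± 18.0 in Hanhui3 and 1993 ± 138 in Huhan7B (SD, n = 3). OsChlH (Os03g0323200), of chlorophyll synthesis, differed by -3.32 ± 0.03 and OsTIP1 (Os01g0975900), a tonoplast aquaporin, by -3.66 ± 0.04 in log2 (SE, n = 3). The dehydrin LIP9 (Os02g0669100) was higher by 3.08 ± 0.06 (SE, n = 3).

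Under drought 11 lists were called and 6 held with an estimated correlation. Photosystem genes were lower in 38 of 64 cases and higher in 14 (adjusted p = 5.04e-20), and aquaporin genes lower in 16 of 28 and higher in 4 (adjusted p = 1.82e-08), both as many adjusted over the list alone. Calvin cycle genes were lower in 17 of 32 cases and higher in 7 (17 and 8 adjusted over the list alone; adjusted p = 1.82e-08). LEA and dehydrin genes were higher in 21 of 24 cases, as many adjusted over the list alone, with a median of 2.16 (adjusted p = 7.58e-06). Stem and vascular markers were higher in 22 of 27 cases and lower in 1, as many adjusted over the list alone (adjusted p = 0.000863). For chlorophyll synthesis genes, 13 of 29 lower and 11 higher, as many adjusted over the list alone, the median was 0.0, or -0.19 with median-ratio scaling, while the mean of -0.62 and the test pointed down (adjusted p = 9.79e-05).

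The calls lost with an estimated correlation under drought were those of 5 lists. Cytosolic ribosomal protein genes were higher in 193 of 228 cases and lower in 4 (195 and 4 adjusted over the list alone; adjusted p = 1.33e-05; adjusted p = 0.267 with an estimated correlation), with a median of 0.44. Median-ratio scaling gave 104 higher and 14 lower and a median of 0.14 (adjusted p = 0.00526). TCA cycle genes were higher in 29 of 34 cases and lower in 2 (adjusted p = 0.0104; adjusted p = 0.127 with an estimated correlation), and glycolysis genes higher in 36 of 47 and lower in 4 (adjusted p = 0.0151; adjusted p = 0.107 with an estimated correlation), both as many adjusted over the list alone. Abscisic acid metabolism genes, 8 of 15 higher and 6 lower, as many adjusted over the list alone, had a median of 0.30 but a mean of -0.28 and a test pointing down (adjusted p = 0.0437; adjusted p = 0.267 with an estimated correlation). That call was lost with median-ratio scaling (0.336; median 0.012), without Huhan7B drought replicate 2 (0.0507) and without Hanyou73 drought replicate 2 (0.0558). Nitrogen assimilation genes, 8 of 21 higher and 8 lower, as many adjusted over the list alone, had a median of -0.043, a mean of 0.033 and a test pointing down (adjusted p = 0.0437; adjusted p = 0.0885 with an estimated correlation). That call was lost with an FPKM of at least 5 (0.169), median-ratio scaling (0.175; median -0.29), no filter (0.117) and without Hanyou73 drought replicate 3 (0.0541). Antenna proteins had 14 of 16 members at least 2-fold lower against 0.6 expected (Fisher's exact test, adjusted p = 4.64e-17). In total 16416 genes differed, 13184 higher and 3232 lower, and 3593 by at least 2-fold. The median gene was higher by 0.30 in log2, and median-ratio scaling, which puts it at 0.035, gave 7678 higher and 6398 lower, with 669 genes called in the opposite direction.

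Genes outside the range of both parents, called against each in the same direction, were counted next. In water the early light-inducible protein gene Os07g0178800, of pigment protection in the chloroplast, stood at 3703 ± 215 FPKM in the hybrid against 52.1 ± 3.40 in Hanhui3 and 59.9 ± 5.04 in Huhan7B (SD, n = 3). OsMT1b (Os03g0288000), a metallothionein, stood at 1089 ± 86.2 against 32.0 ± 2.14 and 34.8 ± 3.58, and OsLOX1 (Os02g0194700), a chloroplast lipoxygenase, at 3.02 ± 0.183 against 291.8 ± 48.7 and 182.1 ± 1.73 (SD, n = 3). Under drought OsBBX19 (Os06g0298200), a CONSTANS-like zinc finger protein, stood at 130.3 ± 3.61 FPKM in the hybrid against 0.733 ± 0.162 and 0.560 ± 0.182 (SD, n = 3). DTH2 (Os02g0724000), of the same family, stood at 103.1 ± 1.52 against 1.43 ± 0.306 and 1.30 ± 0.136 (SD, n = 3). The CP26 antenna gene ASCAB9-A (Os11g0242800) lay below both parents, at 178.3 ± 1.31 against 3781 ± 72.5 and 4078 ± 315 FPKM (SD, n = 3). Of the 64 photosystem and light-harvesting genes, 35 lay below both parents in water and 35 under drought, while 7 and 11 lay above. Antenna proteins of KEGG at least 2-fold below both parents under drought numbered 13 of 16 against 0.4 expected (Fisher's exact test, adjusted p = 9.92e-18).

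In water 8790 genes lay outside both parents, 5971 above and 2819 below, and under drought 10621 did, 8853 above and 1768 below. At least 2-fold, these were 2223 and 2163 genes. Independent lists of the same sizes would share 3914 above and 1469 below in water and 6599 and 574 under drought. In both conditions 3886 genes lay above and 1019 below, against 2340 and 221 for independent lists. Both comparisons use the same hybrid libraries, and in 20 simulations of unchanged groups limma called 0 genes, with a mean of 248.1 in water and 243.2 under drought at an unadjusted p under 0.05. No group differed in these simulations, so the 0 does not cover genes that differ between the hybrid and 1 parent alone. Across genes, which are not independent replicates, the differences from either parent correlated with r = 0.532 in water and 0.547 under drought, against 0.499 and 0.481 in the simulations. Their covariance was 0.502 and 0.445 against 0.0157 and 0.0148. The simulated covariance holds noise alone, so any difference between genotypes raises the real one. Both differences also contain the hybrid's own mean. A correlation and an overlap beyond independent lists can therefore arise for any genotype in its place, and neither is evidence of something particular to a hybrid. The 3 hybrid libraries per condition were not split, since each part could not keep 2, so part of any excess may come from the shared libraries. Median-ratio scaling gave 4902 above and 4056 below in water and 4518 and 3701 under drought, and equal sums gave 7489 and 2115 in water and 9915 and 1546 under drought.

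**Figure D4:**
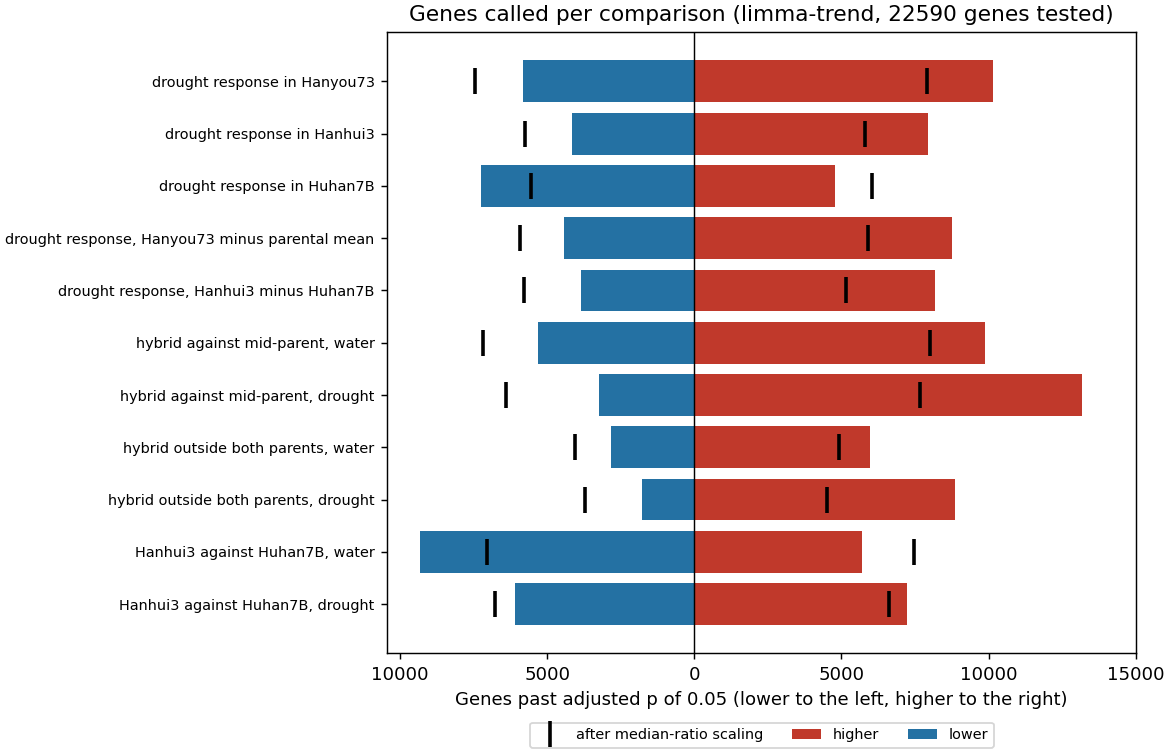
Genes past an adjusted p of 0.05 in each comparison (limma-trend, 22590 genes tested), with those lower to the left and those higher to the right of zero, and black ticks for the counts with median-ratio scaling. The hybrid against mid-parent under drought has 13184 higher and 3232 lower genes, and 7678 and 6398 after scaling.

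Genes expressed in a single parent were followed into the hybrid, with 3 libraries at an FPKM of at least 1 counted as on and 3 under 0.1 as off. In water 223 genes were on in Hanhui3 and off in Huhan7B, and the hybrid had 150 of them on (67.3%), 10 off and 63 in between. Of 221 genes with the opposite pattern the hybrid had 111 on (50.2%), 51 off and 59 in between. Under drought the hybrid had 103 of 174 Hanhui3 genes on (59.2%) and 9 off, and 55.5% of the Huhan7B genes on and 31 off. A further 59 genes in water and 79 under drought were on in the hybrid and off in both parents, and 10 and 3 were the reverse. Off here means not detected at this depth, since an FPKM of 0.1 is a few reads or none.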

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

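Flagged results are responses that differ between genotypes, by a test of the difference itself. The tests of splits, of the sampling hour, of parental leaves, of the authors' scaling and of neighbouring genes were chosen after the results were seen, and the other tests before.

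The hybrid's drought response differed from the parental mean in 13168 genes and the parents' responses differed from each other in 12035. The called lists of the first difference had median log2 differences of 1.471 for LEA and dehydrin, 1.143 for stem and vascular markers, 1.125 for defence and 0.515 for starch synthesis. Ribosomal protein genes had 0.481, the Calvin cycle 0.461 and dividing-cell markers 0.387. Lower medians were -0.527 for chlorophyll breakdown, -0.297 for lignin, -0.252 for the clock, -0.234 for jasmonate, -0.114 for antioxidant enzymes and -0.051 for heat shock proteins. At least 2-fold, 27 glutathione metabolism genes were lower and 12 diterpenoid genes higher in the hybrid's response, and 46 genes of protein processing in the endoplasmic reticulum were higher in Hanhui3's response than in that of Huhan7B.

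Among markers, the hybrid's response minus the parental mean was 2.90 in log2 for LEA3, 4.30 for RAB16A, 1.65 for NCED3, 0.58 for P5CS1, 1.49 for SNAC1 and 0.84 for bZIP23. For Rubisco small subunits it was 1.84 (Os12g0274700), 1.35 (RbcS3), 1.35 (Os12g0292400) and 1.40 (RbcS5). For carbon and sugar genes it was -1.10 (PPDKB), 0.33 (AGPL1), 0.99 (AGPL3), 0.30 (SPS1), -0.72 (SUT1), -0.85 (SUT2), -1.21 (SWEET13), -1.68 (SWEET14) and 2.91 (SWEET15). With median-ratio scaling the calls of AGPL1 (0.157, adjusted p = 0.0717) and SPS1 (0.151, adjusted p = 0.167) were lost. OsDREB1B had 6.41, ERF102 6.28, JIOsPR10 5.14, OsCML21 -5.25, SGR -3.82, OsPAO -1.88 and OsHsp71.1 -3.47. RAB16A and SWEET15 were listed at 0 in watered parents and LEA3 was near zero there, so their values depend on the pseudocount.

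Between the parents, Hanhui3 minus Huhan7B was -3.92 for LEA3, 0.98 for RAB16A, -2.58 for NCED3, 0.74 for P5CS1, -0.71 for SNAC1 and 0.32 for bZIP23, whose call was lost with median-ratio scaling (0.105, adjusted p = 0.435). Rubisco genes had -0.17 (Os12g0274700), 0.57 (RbcS3), 0.71 (Os12g0292400), -1.51 (OsRcaII) and 0.11 (RbcS5), the last turning to -0.13 with median-ratio scaling. The call of RbcS5 (Os12g0291400) was lost without a filter (adjusted p = 0.056), with only the groups compared (0.0548) and with equal sums (0.122). It was also lost without Huhan7B drought replicate 2 (0.0519) and without Huhan7B water replicate 1 (0.0599). Carbon and sugar genes had -0.89 (PPDKB), -0.77 (AGPL1), 1.75 (AGPL3), 1.48 (SUT1) and -1.11 (SWEET15), with SWEET15, RAB16A and LEA3 again resting on the pseudocount. OsPR1b had 4.44, OsLOX11 4.47 and CP -6.26.

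Of 64 light-harvesting genes, 35 lay below both parents in water and 35 under drought, while 7 and 11 lay above. Of 10 clock genes, 6 lay above both parents and 3 below in water, and 4 and 4 under drought. Of all 22590 genes tested, 5971 lay above and 2819 below in water, and 8853 and 1768 under drought (38.9% and 47% outside both). Parental leaves in place of the hybrid are argued against, since the hybrid libraries had between 50.2% and 67.3% of single-parent genes on, from either parent. The authors' scaling of the libraries is argued against for the light-harvesting genes. Under any factor on the hybrid libraries, at least 37.5% of the 64 members stayed 2-fold outside both parents. As deposited, 10.1% of all genes in water did (exact binomial p = 5.68e-09). The 37.5% belongs to a factor of 1.74, under which the share of all genes was not computed, so this p-value sets unlike scalings side by side. For the clock genes the scaling stays undecided, with 30% of members, or 3 of 10 (exact binomial p = 0.0723 in water and 0.0681 under drought), after a first version of this test, on genes below both parents alone, was void. The binomial tests take genes as independent trials, so these p-values do not measure the spread between libraries. The labels state the same time of day for all groups. From the values alone a later sampling hour of the hybrid leaves stays open, with 77.8% of clock genes called in both conditions (7 of 9) on the same side of mid-parent. Hour and genotype cannot be told apart by these values, and a genotype effect stays open as untested.

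Of the 221 genes on in Huhan7B and off in Hanhui3 in water, 51 were off in the hybrid. Too few reads in the hybrid libraries are argued against by a median of 21 reads expected at an equal parental share, with 40 of 51 genes at 10 or more. A state of the leaves in water alone stays undecided. Of these genes, 68.6% (35 of 51) were also off in the hybrid under drought. That count did not require Huhan7B to express them under drought, so genes silent in all droughted leaves are part of it. A seed parent of the hybrid that differs from Huhan7B in chromosome segments could account for 19 neighbouring pairs both off, against 10.95 in random orders (one-sided permutation p = 0.00238). Other reasons for nearby genes to be off together were not tested, so the p-value does not single out this one. Neighbours were taken in order among the 221 genes alone. That order used locus numbers after a first version with reference places was void, with 15.8% of genes placed (3 pairs against 2.66, permutation p = 0.541).

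The median gene was higher in the hybrid than at mid-parent under drought, by 0.30 in log2. A gene length bias is argued against, with medians of 0.287 to 0.351 over the classes of length. A smaller share of FPKM taken by the 100 most abundant genes left a median of 0.123 when removed, so it may account for part and stays undecided. That share was 21.0% in the droughted hybrid, 34.8% in Hanhui3 and 34.2% in Huhan7B. A genotype effect on total RNA was not tested.

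Libraries were also split in other ways to see how often other assignments to groups reach the real counts. With 10 splits the number is too small for a share under 0.05, and in each such case only 1 split, the real one, reached its count. The real counts and the highest of the other splits were 15977 and 1 for Hanyou73, 12098 and 2 for Hanhui3, 12037 and 2 for Huhan7B, and 15009 and 1 in water and 13313 and 1 under drought for the parents. For lists they were 9 and 7, 7 and 3, and 17 and 15 in Hanyou73, Hanhui3 and Huhan7B, with medians of 5, 1 and 13 over the other splits, though these called at most 1, 2 and 2 genes, so a list called with the preset correlation alone is weak evidence.

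With 100 splits, a share under 0.05 reached the real count in all cases but the last. For the hybrid against mid-parent it was 1 split in water (15190, highest other 14893) and 1 under drought (16416, 12825). Outside both parents it was 3 splits in water (8790, highest other 9069) and 1 under drought (10621, 10021), so in water another split exceeded the real count. For the hybrid's response minus the parental mean it was 1 (13168, highest other 12201), and for its lists 2 (13, highest other 14). For the parents' difference in response it was 1 (12035, highest other 6041), and for the overlap 1 (3442, highest other 0). Lists against mid-parent in water reached 11 in 1 split (highest other 10). Under drought 13 of 100 splits reached 11 lists, with a highest of 13, so chance cannot be excluded there. The other splits called a median of 0 genes, so the real labels stand out from splits that mix groups wherever any groups differ. Among the 100 splits only the mirror image of the real labels was barred. A split could thus keep a group whole under another label, such as a parent named as the hybrid. Whether the highest other counts came from such splits was not checked, so these shares show nothing particular to the hybrid. Chance differences between plots cannot be excluded, since each library was a pool of plants that shared a plot.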

How the results depend on the processing

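Median-ratio scaling, a pseudocount of 0.1, an FPKM of at least 5 and equal sums were chosen after the data were seen. The DESeq2 Wald test and edgeR with TMM, RLE or filterByExpr were not run, since counts were not used here. The total number of genes called in each comparison stayed within 1.5 times under scaling, no filter, the groups compared alone, a pseudocount of 0.1, an FPKM of at least 5 and equal sums. The counts by direction did not: with median-ratio scaling, 13184 higher and 3232 lower genes against mid-parent under drought became 7678 and 6398, and 8853 above and 1768 below both parents became 4518 and 3701. Equal sums gave 14096 and 2913, and 9915 and 1546. The arithmetic mid-parent gave 14984 genes in water and 16086 under drought. Depth limits genes near the floor, where an FPKM of 0.1 is a few reads or none.

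A threshold of 2-fold left 4594, 1611 and 1681 genes for Hanyou73, Hanhui3 and Huhan7B and 249 in the overlap, fewer by construction. It left 2996 for the hybrid minus parents, 2493 for the parents' responses, 3829 and 3593 for mid-parent in water and drought, 2223 and 2163 outside both parents, and 3822 and 3188 between the parents. Other on and off levels moved the single-parent counts by construction, to 267 and 196 when stricter (on at 2, off under 0.05) and 764 and 738 when looser (on at 0.5, off under 0.2).

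An estimated correlation left 3 called lists in Hanyou73, 0 in Hanhui3 (7 by camera at an unadjusted p under 0.05, 30 by fry), 5 for the hybrid minus parents, and 4 and 6 against mid-parent in water and drought. The fry directional test, against no change and not against the other genes, gave 28, 30, 31, 28, 30 and 31 for Hanyou73, Hanhui3, Huhan7B, the hybrid minus parents, and mid-parent in water and drought. The cause was not tested.

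Median-ratio scaling turned the sign of OsRcaII in Hanyou73 (-0.109), AGPL1 (-0.121) and SUT2 (-0.042) in Hanhui3 and SUT1 in Huhan7B (0.053), none of them called as deposited, and of RbcS5 between the parents' responses (-0.128, adjusted p = 0.0131). Equal sums turned OsRcaII in Hanyou73 (-0.055) and AGPL1 in Hanhui3 (-0.061). A pseudocount of 0.1 turned SWEET13 between the parents' responses (-0.579, adjusted p = 0.00657). The cause was not tested. With median-ratio scaling the median of the hybrid's response minus the parental mean moved by more than 1.5 times, with no call or direction lost, for antioxidant enzymes (-0.282), the Calvin cycle (0.29), the clock (-0.422), ribosomal proteins (0.311), heat shock (-0.221) and dividing-cell markers (0.217). Scaling also gave calls that the deposited values lack, among them the TCA cycle in Hanyou73 (0.0193), raffinose for the hybrid minus parents (0.0339) and defence against mid-parent under drought (0.000646).

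With single libraries left out, AGPL1 in Hanhui3 ran from -0.048 to 0.064, and the value of SWEET14 (Os11g0508600), drought response, Hanhui3 minus Huhan7B, from -0.228 to 0.024; neither was called. Counts ran from 15131 to 15314 in Hanyou73, 10959 to 11840 in Hanhui3, 11021 to 11534 in Huhan7B and 3197 to 3398 for the overlap.

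The replicate block gave 15874 genes in Hanyou73's response, 11969 in Hanhui3, 11875 in Huhan7B and 12972 for the hybrid minus parents, with 15732, 11788, 11753 and 12817 of them called without it. It changed no call of a list or of a named gene. Replicate numbers do not pair libraries: 0 of 45 pairs with the same number stood over 0.1, and 19 of 45 were best with their own number.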

Other observations

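Of 57 grain genes, 2 passed the filter in the leaves, and their list was not tested. Among these Glua2 (Os10g0400200), a glutelin of the grain, stood at 8.91 FPKM in watered and 9.56 in droughted Hanyou73, 6.66 and 9.10 in Hanhui3, and 9.22 and 9.24 in Huhan7B.

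Of 10 clock genes, 6 lay above both parents and 3 below in the watered hybrid. CCA1 (Os08g0157600), a morning clock gene, stood at 5.27 ± 0.359 FPKM in the watered hybrid against 55.5 ± 0.964 in Hanhui3 and 47.6 ± 2.12 in Huhan7B (SD, n = 3). OsPCL1 (Os01g0971800), of the evening complex, stood at 428.7 ± 10.0 against 4.02 ± 0.708 and 14.6 ± 1.66 (SD, n = 3). The clock list was not called against mid-parent in water (camera adjusted p = 0.631), with 6 of 10 members higher and 4 lower.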
